A study of Homo sapiens with 21 samples.

How the data were processed

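Total RNA of peripheral blood mononuclear cells (PBMC) was sequenced from 7 patients who received a hematopoietic stem cell transplant for neuroblastoma. Of these, 4 patients had thrombotic microangiopathy (TMA), an injury of small vessels with clotting and loss of red cells and platelets, and 3 did not. Each patient gave 3 libraries, 21 in all: baseline, onset and resolution for the patients with TMA, and baseline, low ALC and recovery for the patients without it. ALC is an abbreviation that the labels do not expand. The labels of that time point name both low ALC and the TMA time point, and they do not say how it was chosen. Per the submitters' processing notes, bcl2fastq, TopHat and edgeR were used with the genome build hg19; versions, the read counter and its annotation are not given in the sources used here. The deposited tables hold raw whole-number read counts per Entrez gene ID, 1 column per library, as tested on the values; they were used without further scaling. The patients with TMA are in 1 table and the patients without it in another, so TMA status and table cannot be told apart in any comparison of levels between the arms. The tables hold the same 26347 gene IDs, of which 26204 were matched to a gene symbol of the human reference; these carried 99.86% of the counts. XIST, TSIX and Y-linked genes (108 genes) were removed before any test. No genomic positions are given, because the counts were made on hg19 and the reference at hand is a later build.

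The libraries held 9554929 to 27971337 counts. Binomial intervals (Wilson, 95%) given for a share of a single library cover counting error only, since reads without molecular identifiers are not independent molecules. Every pair of libraries of a group was checked for duplication: the lowest chi-square per degree of freedom between 2 libraries of a group was 34.96 (genes with a summed count of at least 20), so no pair differed by counting noise alone.

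Comparisons, tests, gene lists and the genes to be named were set before the data were examined. Genes were filtered with filterByExpr by group, scaled by TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 (estimateDisp, glmQLFit with robust=TRUE, glmQLFTest) in R 4.3.3. P-values were adjusted by Benjamini-Hochberg and called at an adjusted p of 0.05. Comparisons within an arm used the libraries of that arm with the patient as a block. Differences between the arms in the change from baseline (interactions) used all 21 libraries with the patient block, which removes any constant difference between the tables. Levels at baseline and at the second time point were also compared between the arms, without a block. The pairing comes from the labels, which give the same patient at 3 time points. Libraries of the same patient also had correlated deviations from their group means (mean r 0.178 to 0.36 across genes, which are not independent replicates). The values for libraries of different patients (-0.18 to -0.0556) are no separate evidence. Deviations from a group mean sum to 0, which pushes those values below 0. Standard errors (SE) of log2 fold changes were taken as the fold change over the square root of F.

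Of 30 gene lists fixed beforehand, 28 had at least 5 tested members and were tested with camera at the preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. No list of any comparison passed with the estimated correlation; the lowest adjusted p values are given with the comparisons. The 28 lists were type I interferon response, interferon gamma response, complement components, receptors and regulators, immature neutrophil granules, mature neutrophils, classical and non-classical monocytes, macrophages, dendritic cells, T cells, NK and cytotoxic cells, B cells, plasma cells, platelets, erythroid cells, haematopoietic progenitors, cell proliferation, MHC class II, inflammatory cytokines, glucocorticoid response, p53 targets, haem and oxidative stress, endothelial cells, coagulation, immediate early genes and ribosomal proteins. A neuroblastoma list had 0 to 3 measured members and a list of mitochondrially encoded genes had 0 members in the tables, so neither was tested. Where a list's median or mean and camera's direction differed in sign (0 to 4 lists of a comparison by the median), the list had not passed. A list score was the mean log2 CPM of its members in a library. Changes of the score per patient were compared between the arms by an exact two-sided permutation of the 7 patients (35 splits, smallest possible p 0.0286). This test was chosen after seeing the data. With that smallest p no single list could pass after adjustment over 28 lists, so its failure to pass there does not tell.

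Named genes were, per comparison, the 6 with the largest change upward and the 6 downward among those with an adjusted p under 0.05, a mean log2 CPM of at least 1 and the same sign in every patient (or no overlap of the groups). Up to 4 members of each list past the threshold were added, or, where none passed, up to 2 with the smallest p. A fixed panel was added in every comparison, which included IFI44L, MX1, ISG15, CXCL10, C1QA, C1QB, C1QC, C2, CFB, CFD, C3AR1, SERPING1, CD46, CD55, CD59, CD163, HP, HMOX1, PPBP, CD3D and CD14. Genes whose level can mark a person's genotype or clones were not named.

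Alternatives set beforehand were DESeq2 1.42.0 (Wald test, own size factors), RLE in place of TMM, no low-count filter, no patient block, a joint fit of all 21 libraries, each patient left out in turn, and, for lists, an estimated correlation and fry on voom values. Added after seeing the data were limma-voom (limma 3.58.1), edgeR with bias-adjusted deviances, removal of the haemoglobin genes, and the removal of 3 single libraries in turn. Permutation tests were run in R, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The procedure was tested on simulated counts drawn with the real means, dispersions and library sizes: in the design of TMA onset against baseline, 25% of genes changed by a log2 fold of 1, 57.6% of those changed by 2 and 74.2% of those changed by 3 were recovered, with 7.14% unchanged genes among the calls. For the interaction at onset the recovery was 2.94%, 36.4% and 68.2%. The genes were drawn independently of each other, few were changed, and the patient effects had an assumed size. These shares therefore hold for the simulation and are not the recovery in the real data, where genes of a list move together.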

Results

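RNA of peripheral blood mononuclear cells was counted per gene in 21 libraries from 7 transplant patients. The patients with TMA (n = 4) were sampled at baseline, at onset and at resolution, and the patients without TMA (n = 3) at baseline, at low ALC and at recovery. The libraries with TMA held 9554929 to 22786166 counts, and those without TMA 11552420 to 27971337. The haemoglobin genes took 0.007% to 8.95% of the counts with TMA and 0.0927% to 6.19% without it. The highest shares were 8.95% in TMA onset replicate 1 (Wilson 95% interval 8.94% to 8.97%) and 6.19% in the no-TMA recovery replicate 1 (6.18% to 6.20%). The series title names interferon and complement pathways in TMA, so the question followed here is whether the genes of those pathways changed with TMA. The patients without TMA, sampled at baseline and at time points labeled low ALC and recovery, were set against them. Log2 fold changes and their SE are from the edgeR fit, and list scores give the number of patients that showed a list's direction.

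At the onset of TMA the complement genes C1QC (Entrez 714) and C1QB (713) were higher than at baseline, with log2 fold changes of 4.51 (SE 1.25) and 3.95 (SE 1.12), in 4 of 4 patients. C1QC stood at 2.04 ± 0.649 CPM (SD, n = 4) at baseline and at 66.0 ± 51.7 at onset. In the patients without TMA, C1QC stood at 3.40 ± 1.75 CPM (n = 3) at baseline and at 25.9 ± 11.5 at low ALC. C2 (717) was higher at onset by 1.67 (SE 0.541), CFD (1675) by 0.89 (SE 0.249) and the C1 inhibitor gene SERPING1 (710) by 2.73 (SE 0.839). Their edgeR adjusted p values were 0.177, 0.14 and 0.171, and their DESeq2 adjusted p values 0.015, 0.0204 and 0.00106. The complement receptor genes C5AR1 (728) and C3AR1 (719) were higher by 1.21 (SE 0.257) and 1.45 (SE 0.388). Among the membrane regulators, CD55 was higher by 0.60 (SE 0.235), CD46 by 0.46 (SE 0.202) and CD59 by 0.49 (SE 0.318), while CFB was higher by 0.51 (SE 0.456). No gene of the 15127 tested passed with edgeR (2801 had an unadjusted p under 0.05, lowest adjusted p 0.0987) or with limma-voom, whereas DESeq2 called 1070, of which 419 were higher and 651 lower.

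As lists, the complement components were higher at onset (median log2 fold change 0.55, 11 of 14 measured members), as were the complement receptors (0.66, 10 of 12) and the complement regulators (0.49, 7 of 8). With camera the adjusted p values were 0.000108, 0.00136 and 0.0299; with an estimated correlation they were 0.174, 0.174 and 0.351. Adjusted over the list alone, 6 components and 3 receptors passed, and 0 regulators. The regulators' camera call ended without TMA replicates 2, 3 or 4 (adjusted p 0.057, 0.0683 and 0.0773) and without the library TMA onset replicate 3 (0.179). The macrophage list, whose markers are carried by cells that also express C1q, was higher with them (median 1.40, 13 of 13, camera adjusted p 3.38e-06, estimated 0.222), as were classical monocytes (0.59, 13 of 14, 0.000171, estimated 0.333) and non-classical monocytes (0.62, 11 of 12, 0.0407, estimated 0.551). The scores of components, receptors, macrophages and classical monocytes were higher in 4 of 4 patients, that of regulators in 3 of 4 and that of non-classical monocytes in 2 of 4. MERTK (10461), a receptor for dying cells, was higher by 2.55 (SE 0.47, 4 patients), from 9.03 ± 3.64 to 57.4 ± 29.3 CPM, against 9.91 ± 0.944 to 46.3 ± 19.5 CPM without TMA. MSR1 was higher by 2.85 (SE 0.618) and CD163 by 2.19 (SE 1.01). The haem oxygenase gene HMOX1 (3162) was higher by 1.27 (SE 0.276, DESeq2 adjusted p 0.00104), from 102 ± 37.1 to 246 ± 34.7 CPM, and the iron store gene FTL by 0.89 (SE 0.217).

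All 49 measured members of the type I interferon response were higher at onset, with a median log2 fold change of 1.16 (camera adjusted p 8.05e-13, 0.388 with an estimated correlation). The interferon gamma response was higher in 30 of 32 members (median 0.96, camera adjusted p 6e-07, estimated 0.388), of which 4 passed adjusted over the list alone, against 0 of the type I list. DESeq2 called 8 type I members, all higher. The macrophage adhesion gene SIGLEC1 (6614) was higher by 2.85 (SE 0.765, DESeq2 adjusted p 0.000111) and IFITM3 by 2.08 (SE 0.583). IFI44L was higher by 1.90 (SE 0.945), ISG15 by 1.72 (SE 0.957) and MX1 by 1.33 (SE 0.85), each in 3 of 4 patients, and CXCL10 by 2.33 (SE 1.91) in 2 of 4. The direction and size differed between patients: the type I score was higher in 3 of 4, with a mean change of 1.16 ± 1.58 log2 CPM (SD, n = 4) and a range of -0.627 to 3.18, and the gamma score was higher in 3 of 4. Without the library TMA onset replicate 3 the median of the type I list was 0.41 (camera adjusted p 0.00024).

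B cell, plasma cell and NK cell genes moved the other way at onset. The B cell list was lower in 13 of 13 members (median -4.42, camera adjusted p 8.05e-13, estimated 0.315), the plasma cell list in 9 of 10 (-3.07, 2.58e-08, estimated 0.174) and the NK cell list in 15 of 16 (-1.04, 6e-07, estimated 0.351). Adjusted over the list alone, 11, 6 and 2 members passed. MZB1 (51237), an antibody secretion gene, fell by 3.44 (SE 0.673, DESeq2 adjusted p 1.96e-07), DERL3 fell by 2.95 (SE 0.515, 3.99e-07), CD72 (971) fell by 3.72 (SE 0.979, 0.0016) and KLRF1 (51348) fell by 2.74 (SE 0.602, 1.99e-05), each past DESeq2's threshold in 4 patients. T cell genes did not move together (12 of 18 higher, median 0.15, camera adjusted p 0.559, direction down), with CD3D higher by 0.36 (SE 0.665). The dendritic cell list was lower in 10 of 11 members (median -1.52, camera adjusted p 0.000892, estimated 0.333). MHC class II genes were lower in 10 of 10 (-0.55, 3.39e-05, estimated 0.351), with HLA-DOA at -2.44 (SE 0.58) and CIITA at -0.85 (SE 0.255). The B cell, plasma cell, NK cell, dendritic cell and MHC class II scores were lower in 4 of 4 patients. Mature neutrophil genes were higher in 11 of 11 (0.81, 0.0303, estimated 0.507; score higher in 3 of 4 patients). Immature neutrophil granule genes were higher in 14 of 14 (0.94, 0.0169, estimated 0.462), but their score was higher in 2 of 4 patients, by 3.83 in replicate 4 and 0.578 in replicate 2, and changed by -0.223 and -0.373 in the others.

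**Figure D1:**
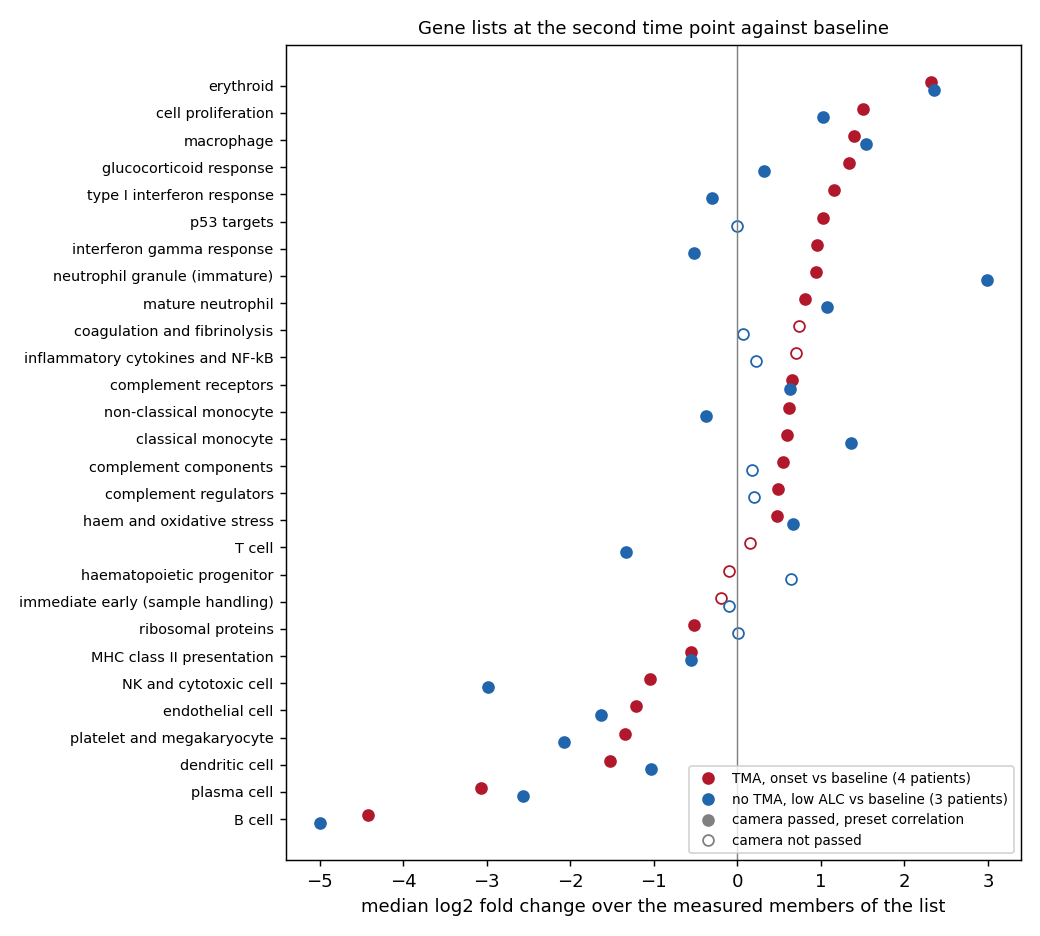
Median log2 fold change over the measured members (x axis) of the 28 tested gene lists (y axis), for TMA onset against baseline (red, n = 4 patients) and for low ALC against baseline without TMA (blue, n = 3); filled points passed camera at the preset correlation and open points did not. The type I interferon list sat at 1.16 with TMA and at -0.31 without it, whereas the macrophage list sat at 1.40 and 1.54.

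From onset to resolution the type I interferon, complement component and complement receptor scores were lower in 4 of 4 patients. The regulator score was lower in 3 of 4 and the interferon gamma score in 2 of 4 (changes of -2.19 to 0.602). Without TMA the component and receptor scores also fell in every patient, from low ALC to recovery. The mean changes with and without TMA were -0.751 and -0.405 for components (exact permutation p 0.371). For receptors they were -0.504 and -0.513 (exact permutation p 0.971), and for type I interferon -1.23 and 0.693 (exact permutation p 0.171). With TMA, all 49 type I interferon members were lower at resolution than at onset (median -1.18, camera adjusted p 6.72e-19, estimated 0.331). Among them were SIGLEC1 at -3.44 (SE 0.729, 4 patients, DESeq2 adjusted p 5.68e-06) and IFI44 at -2.18 (SE 0.631, DESeq2 adjusted p 0.00542). IFI44L stood at -2.52 (SE 0.902), ISG15 at -2.11 (SE 0.913) and MX1 at -1.94 (SE 0.808). The interferon gamma list was lower in 28 of 32 members (median -0.45, 6.84e-05, estimated 0.462), a call that ended without TMA replicate 3 (adjusted p 0.748) and without the library TMA onset replicate 3 alone (0.779). Complement components were lower in 12 of 14 members (median -0.71, camera adjusted p 5.2e-06, estimated 0.151) and receptors in 9 of 12 (-0.68, 0.00041, estimated 0.151). C1QC stood at -2.87 (SE 1.19), C2 at -1.57 (SE 0.565, 3 of 4 patients), CFD at -0.85 (SE 0.252), SERPING1 at -2.45 (SE 0.852) and C3AR1 at -1.37 (SE 0.389). The regulators were lower in 7 of 8 (median -0.51, 0.0787); they passed without TMA replicate 1 (0.00309), without TMA replicate 2 (0.0282) and without the library TMA onset replicate 1 (0.00175). No gene passed with edgeR (1912 had an unadjusted p under 0.05, lowest adjusted p 0.277) or limma-voom, and DESeq2 called 438 (204 higher, 234 lower). A wrong labeling of the same libraries gave 423 DESeq2 calls, so the DESeq2 count here is little above that of a wrong labeling.

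Macrophage genes were lower at resolution than at onset in 12 of 13 members (median -1.37, camera adjusted p 3.73e-07, estimated 0.151), with MERTK at -2.28 (SE 0.464). Classical monocyte genes were lower in 13 of 14 (-0.76, 9.03e-08, estimated 0.151), with FPR1 at -1.23 (SE 0.247), and immature neutrophil genes in 14 of 14 (-1.43, 4.67e-05, estimated 0.331), with OLFM4 at -4.00 (SE 1.19). HMOX1 changed by -1.07 (SE 0.274, DESeq2 adjusted p 0.0151). Plasma cell genes were higher in 9 of 10 (median 2.18, 3.23e-07, estimated 0.151), with TNFRSF17 at 3.96 (SE 0.989, DESeq2 adjusted p 0.000704). B cell genes were higher in 13 of 13 (2.82, 5.2e-06, estimated 0.35), NK cell genes in 16 of 16 (0.91, 1.08e-06, estimated 0.331), with KLRF1 at 2.29 (SE 0.592), and T cell genes in 18 of 18 (0.49, 0.000629, estimated 0.462), with TCF7 at 1.43 (SE 0.435). MHC class II genes were higher in 10 of 10 (0.40, 0.000553) and dendritic cell genes in 9 of 11 (0.57, 0.0186, estimated 0.35). The scores differed between patients: NK cells were higher in 2 of 4, and replicate 3 changed most, by 3.65 for NK cells (others -0.276 to 1.17) and by 3.27 for T cells (others -1.0 to 0.367). The B cell, plasma cell, T cell, MHC class II and dendritic cell scores were higher in 3 of 4 patients, the macrophage and classical monocyte scores lower in 3 of 4 and the immature neutrophil score in 4 of 4. Non-classical monocyte (-0.31, 0.15), mature neutrophil (-0.22, 0.466) and proliferation genes (-0.01, 0.898), which were higher at onset, did not pass here.

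Against baseline, the complement and type I interferon lists did not pass at resolution. For type I interferon the list had a median of -0.03 (19 of 49 higher, camera adjusted p 0.558), the components 0.09 (9 of 14 higher, 0.976), the receptors 0.04 (6 of 12, 0.698) and the regulators 0.21 (0.257). The patients went both ways: the type I score was higher in 1 of 4, with changes of -0.82 to 0.57, and the components score in 2 of 4, with changes of -0.601 to 1.01, so a return to baseline is not shown. SERPING1 was at 0.28 (SE 0.759) and SIGLEC1 at -0.59 (SE 0.735), while C1QC was at 1.65 (SE 1.27). These directions rested on single patients: the type I list passed upward without TMA replicate 1 (adjusted p 0.0382) and downward without TMA replicate 4 (0.00334), the components passed without TMA replicate 2 (0.0437) and the regulators without TMA replicate 3 (0.0206). The interferon gamma list was higher in 27 of 32 members (median 0.29, camera adjusted p 0.00265, estimated 0.702; 0.148 without TMA replicate 1). T cell genes were higher than at baseline in 18 of 18 members (0.59, 1.85e-06, estimated 0.642), with TRAT1 at 1.23 (SE 0.444) and the score higher in 3 of 4 patients. B cell genes were lower in 13 of 13 (-1.58, 6.74e-12, estimated 0.642), with FCRLA at -2.29 (SE 1.48) and CD79B at -1.49 (SE 0.919). Their score was lower in 2 of 4 patients, with changes of -6.72 in replicate 3 and -3.23 in replicate 4, against 0.124 and 0.46 in the others. No gene passed with edgeR (195 had an unadjusted p under 0.05), DESeq2 or limma-voom.

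**Figure D2:**
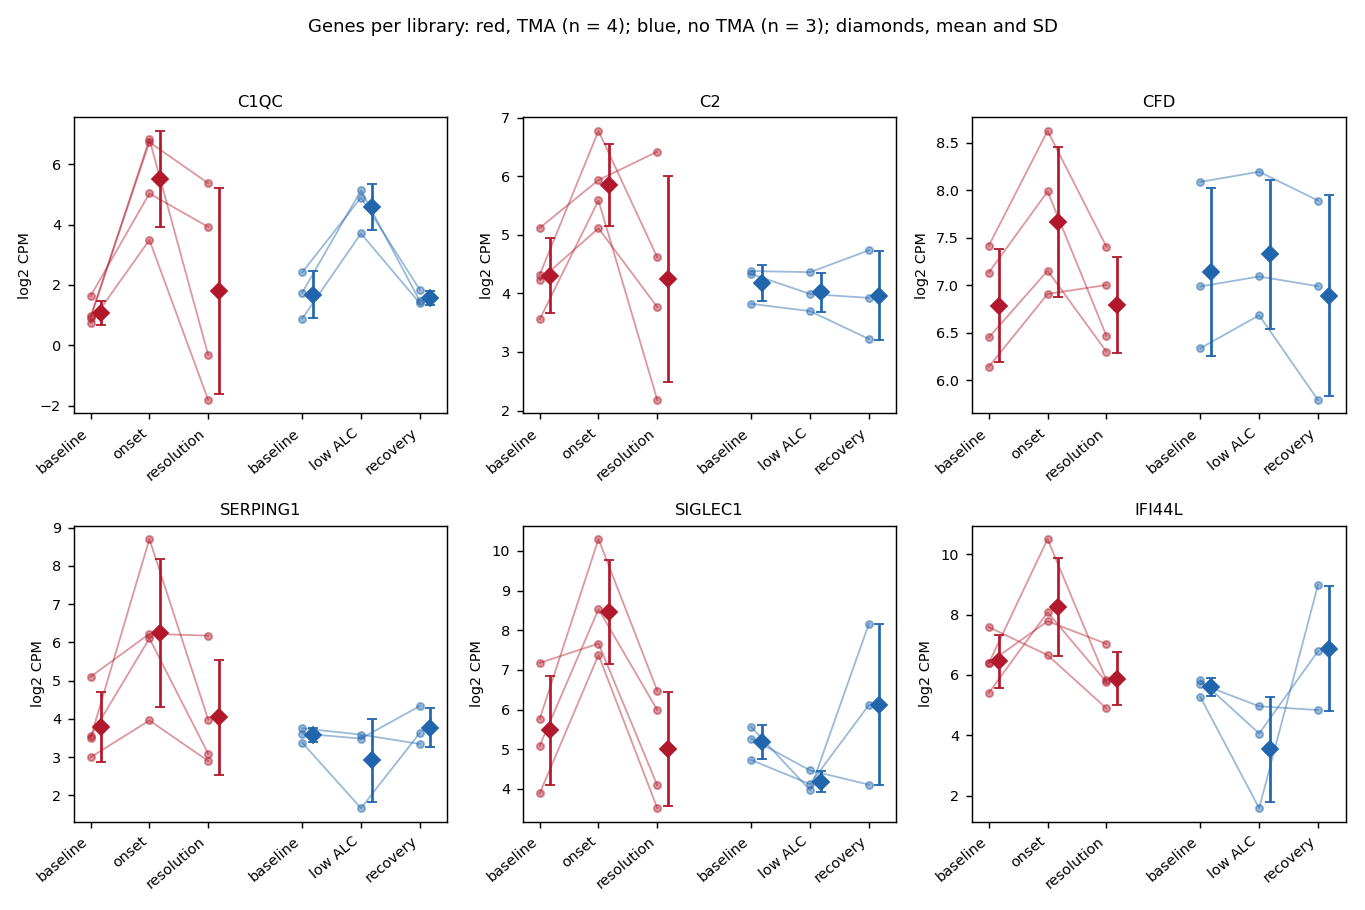
Log2 CPM (y axis) of C1QC, C2, CFD, SERPING1, SIGLEC1 and IFI44L at the 3 time points (x axis); thin lines join the libraries of a patient, and diamonds give the mean with the SD (n = 4 with TMA, n = 3 without). The mean C1QC level was 66.0 CPM at TMA onset and 25.9 CPM at low ALC without TMA, and the mean C2 level 63.2 and 16.4 CPM.

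In the patients without TMA, low ALC was compared with baseline. These libraries are labeled by a low ALC, so they may not stand for the transplant course in general. Changes of the cell lists here can hold the choice of that time point, which was not tested. Immature neutrophil granule genes were higher in 16 of 16 members (median 2.99, camera adjusted p 6.81e-28, estimated 0.0614), with CD177 (57126) at 7.70 (SE 0.751) and MMP8 (4317) at 5.6 (SE 0.66) in 3 of 3 patients. CD177 stood at 0.23 ± 0.24 CPM (SD, n = 3) at baseline, so its fold change starts from a level near 0. C1QC was higher by 2.93 (SE 0.346), C1QB by 1.86 (SE 0.323) and MERTK by 2.09 (SE 0.443), and the macrophage list by a median of 1.54 (12 of 13, camera adjusted p 1.64e-08, estimated 0.343). Classical monocyte genes were higher in 13 of 14 (1.36, 4.45e-11, estimated 0.343), with S100A8 at 2.56 (SE 0.587) and CCR2 at 1.92 (SE 0.443), and non-classical monocyte genes lower in 9 of 12 (-0.38, 0.00945). C2 (-0.18, SE 0.265), CFD (0.18, SE 0.21) and SERPING1 (-0.60, SE 0.436) differed less from baseline than with TMA. The complement components had 8 of 15 members higher (median 0.18, 0.0769, estimated 0.378; 0.0375 without no-TMA replicate 2) and the receptors 10 of 12 (0.63, 0.00288, estimated 0.378; 0.0843 without no-TMA replicate 2). The regulators had 5 of 7 higher (0.20, 0.277).

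Interferon genes were lower at low ALC than at baseline: the type I list in 41 of 49 members (median -0.31, camera adjusted p 0.0197, estimated 0.732; 0.0944 without no-TMA replicate 1) and the gamma list in 24 of 31 (-0.52, 0.0319, estimated 0.511; 0.123 without no-TMA replicate 2). IFITM1 (8519) changed by -2.30 (SE 0.596, DESeq2 adjusted p 0.000947), from 202 ± 68.4 to 44.2 ± 33.3 CPM (n = 3), whereas it went from 193 ± 45.2 to 440 ± 401 CPM (n = 4) with TMA. Plasma cell genes were lower in 9 of 9 members (-2.57, 7.63e-21, estimated 0.121), all 9 adjusted over the list alone, with JCHAIN (3512) at -4.08 (SE 0.417). B cell genes were lower in 13 of 13 (-5.00, 3.97e-13, estimated 0.343), with PAX5 at -6.55 (SE 1.13), and NK cell genes in 16 of 16 (-2.99, 7.78e-14, estimated 0.343), with KLRF1 at -4.47 (SE 0.991). T cell genes were lower in 17 of 18 (-1.33, 1.26e-05, estimated 0.444), with TCF7 at -2.80 (SE 0.52). MHC class II genes were lower in 10 of 10 (-0.56, 0.00184) and dendritic cell genes in 9 of 11 (-1.03, 0.00431). No gene of 15644 passed with edgeR (2562 had an unadjusted p under 0.05, lowest adjusted p 0.075). DESeq2 called 1138 (427 higher, 711 lower) and limma-voom 6, and edgeR called 365 without no-TMA replicate 3, 1 without no-TMA replicate 2 and 3 without the library no-TMA recovery replicate 1.

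From low ALC to recovery 10 genes passed with edgeR, 6 higher and 4 lower, each in 3 of 3 patients. The plasma cell genes JCHAIN (log2 fold change 4.71, SE 0.432, adjusted p 0.0333), MZB1 (4.51, SE 0.523, 0.0385), TNFRSF17 (6.0, SE 0.681, 0.0384) and IGLL5 (7.52, SE 0.819, 0.0384) rose, as did TENT5C (2.74, SE 0.242, 0.0333) and the glucose transporter gene SLC2A1 (2.03, SE 0.229, 0.0384). IGLL5 shares sequence with the immunoglobulin lambda constant genes, so its reads are not certain to be its own. C1QC fell by 3.07 (SE 0.351, 0.0384), CD177 fell by 8.36 (SE 0.826, 0.0384), to 0.135 ± 0.123 CPM, and MMP8 fell by 6.77 (SE 0.719, 0.0384). The fourth, COLEC12, a scavenger receptor gene at a mean log2 CPM of -0.13, fell by 4.90 (SE 0.526, 0.0384) and was chosen after its values were seen. DESeq2 called 1976 genes (956 higher, 1020 lower) and limma-voom 369. The edgeR count was 1, 5 and 16 without no-TMA replicates 1, 2 and 3, and 891, these 10 among them, without the library no-TMA recovery replicate 1, which held the 6.19% share of haemoglobin counts. Removing only the haemoglobin genes left the count at 10, the same genes.

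B cell genes were higher at recovery than at low ALC in 13 of 13 members (median 6.28, camera adjusted p 2.55e-17, estimated 0.285), with PAX5 at 8.75 (SE 1.18), and plasma cell genes in 9 of 9 (3.79, 1.4e-18, estimated 0.152). NK cell genes were higher in 16 of 16 (1.13, 0.00219, estimated 0.745; score higher in 2 of 3 patients) and MHC class II genes in 10 of 10 (0.92, 3.53e-05, estimated 0.385), while T cell genes did not pass (0.21, 0.524). Immature neutrophil genes were lower in 16 of 16 (-3.14, 6.34e-19, estimated 0.152), mature neutrophil genes in 11 of 11 (-1.37, 0.000134; score lower in 2 of 3 patients), classical monocyte genes in 14 of 14 (-2.03, 2e-14, estimated 0.285) and macrophage genes in 11 of 13 (-2.19, 1.26e-10, estimated 0.285). The complement components were lower in 10 of 15 (-0.44, 0.0115, estimated 0.285), with C1QB at -2.46 (SE 0.332) and C1QA at -1.83 (SE 0.334), the receptors in 10 of 12 (-0.90, 0.000254, estimated 0.385), with C3AR1 at -1.88 (SE 0.387), and the regulators did not pass (-0.32, 0.123). Type I interferon genes were higher in 40 of 49 (0.77, 0.000119, estimated 0.774), with ZBP1 at 2.42 (SE 0.399) and IFI44L at 3.43 (SE 1.34, 2 of 3 patients), but not without no-TMA replicate 2 (adjusted p 0.648). The interferon gamma list had a median of 0.17 with camera's direction down (0.864), and passed upward without no-TMA replicate 3 (0.0491).

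At recovery without TMA, B cell genes stood above baseline (13 of 13, median 1.95, camera adjusted p 2.96e-08, estimated 0.563), a difference carried by 1 patient: the score changed by 5.12 in no-TMA replicate 2 and by 0.185 and -0.0212 in the others. NK cell genes stood below it (16 of 16, -1.43, 2.72e-10), with NCAM1 at -2.83 (SE 0.771, DESeq2 adjusted p 0.0122) and KLRF1 at -2.69 (SE 0.851, 0.0477), and so did T cell genes (18 of 18, -1.03, 3.98e-07), with LEF1 at -1.72 (SE 0.463). The NK cell score was lower in 3 of 3 patients and the T cell score in 2 of 3. Macrophage (-0.54, 0.00399), classical monocyte (-0.61, 0.000987) and non-classical monocyte genes (-0.60, 0.000133) were lower, with scores lower in 2, 2 and 3 of 3 patients. Type I interferon genes were higher in 37 of 49 (0.30, 0.000987, estimated 0.682), with IFI27 at 3.47 (SE 1.09, DESeq2 adjusted p 0.0216); its direction was down without no-TMA replicate 2 (0.129), and it did not pass without no-TMA replicate 1 (0.0556) or without the library no-TMA recovery replicate 1 (0.0887). The gamma list was lower in 25 of 31 (-0.41, 0.000464; 0.0772 without no-TMA replicate 3). The components (-0.23, 0.0746; 0.0467 without no-TMA replicate 3) and the receptors (-0.40, 0.0818) did not pass. No gene passed with edgeR (807 had an unadjusted p under 0.05, lowest adjusted p 0.777) or limma-voom, and DESeq2 called 57.

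The interaction asks whether the change from baseline to the second time point differed between the arms, and it is the comparison nearest to the question of the series. The type I interferon list was higher with TMA in 47 of 49 members (median difference 1.55, camera adjusted p 2.23e-23, estimated 0.504) and the gamma list in 29 of 32 (1.18, 6.11e-14, estimated 0.504). IFITM1 differed by 3.17 (SE 0.721, DESeq2 adjusted p 0.0158), LY6E by 2.22 (SE 0.64) and IFI44L by 3.39 (SE 1.65). The complement components were higher with TMA in 14 of 17 members (0.70, 0.000902, estimated 0.454; 0.053 without no-TMA replicate 3), with C2 at 1.84 (SE 0.675), C1R at 1.49 (SE 0.525) and CFD at 0.70 (SE 0.347), while C1QC was at 1.56 (SE 1.44). The receptors had a median near 0 that turned sign under RLE scaling (6 of 12 higher, camera adjusted p 0.775), the regulators did not pass (0.15, 0.513) though their member SERPING1 was at 3.31 (SE 1.07), and the macrophage list was at 0.03 (0.898). NK (16 of 16, 2.01, 5.37e-09, estimated 0.504), T cell (18 of 18, 1.36, 2.25e-06, estimated 0.558) and non-classical monocyte genes (11 of 12, 1.36, 6.71e-05, estimated 0.555) were higher with TMA. Immature neutrophil (17 of 17, -2.16, 7.23e-08, estimated 0.504) and classical monocyte genes (12 of 14, -0.93, 0.000117, estimated 0.504) were lower, with CCR2 at -2.26 (SE 0.625). Compared as score changes per patient, none of these 5 cell lists passed (exact permutation p 0.114 to 0.2). The second time point is TMA onset in 1 arm and low ALC in the other. A difference between the arms there cannot be told apart from that choice of time point. Ribosomal protein genes were also lower with TMA (73 of 76, -0.57, camera adjusted p 1.07e-20, estimated 0.504, exact permutation p of the score 0.0571). The p53 targets were higher (15 of 16, 1.17, 0.00104, estimated 0.617, exact permutation p 0.457). No gene of 16667 passed with edgeR (739 had an unadjusted p under 0.05, lowest adjusted p 0.993) or limma-voom. DESeq2 called 3, which were IFITM1 and, chosen after their values were seen, PDZD4 (4.50, SE 0.839, 0.00138) and APBA2 (2.94, SE 0.632, 0.0179).

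**Figure D3:**
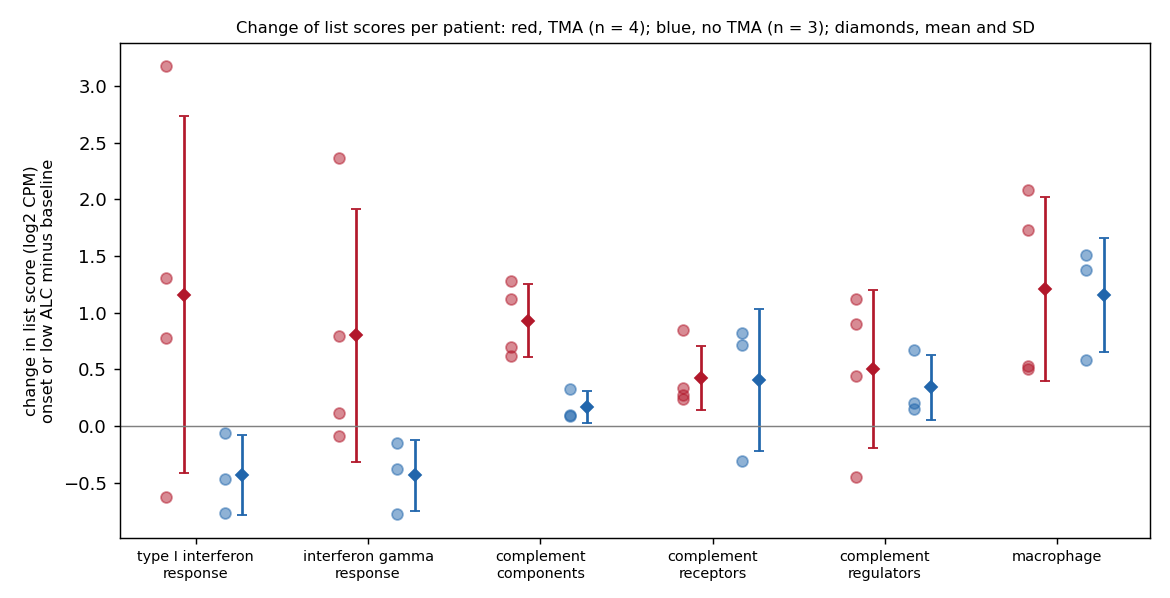
Change of the list score from baseline to TMA onset or to low ALC (y axis, log2 CPM) for 6 lists (x axis), 1 point per patient and diamonds with the mean and SD (n = 4 with TMA, n = 3 without). The complement components score changed by 0.618 to 1.28 with TMA and by 0.0851 to 0.331 without it, whereas the macrophage score changed by 1.21 and 1.16 on average.

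Per patient, the complement components score changed by 0.929 ± 0.32 log2 CPM (SD, n = 4) with TMA and by 0.17 ± 0.139 (n = 3) without it, a difference of 0.759 without overlap of the arms (exact two-sided permutation p 0.0286, the smallest the design allows, and 0.622 adjusted over the 28 lists of this change). The type I interferon score changed by 1.16 ± 1.58 and -0.434 ± 0.354 (exact permutation p 0.143) and the gamma score by 0.8 ± 1.11 and -0.435 ± 0.316 (exact permutation p 0.114). For the receptors the changes were 0.426 ± 0.285 and 0.41 ± 0.628 (exact permutation p 0.943), for the regulators 0.503 ± 0.696 and 0.343 ± 0.289 (exact permutation p 0.714), and for macrophages 1.21 ± 0.812 and 1.16 ± 0.504 (exact permutation p 0.943). Across 14690 genes the changes of the arms correlated with r 0.63 (Spearman's rho 0.544), a correlation across genes, which are not independent replicates. Of 873 genes with an unadjusted edgeR p under 0.05 in both arms, 863 changed in the same direction.

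The interaction at the last time point compares resolution with recovery, each against its baseline. T cell (18 of 18, median difference 1.67, camera adjusted p 9.29e-11) and NK cell genes (16 of 16, 1.45, 9.11e-07) were higher with TMA, with LEF1 at 2.43 (SE 0.772), TCF7 at 2.07 (SE 0.695) and NCAM1 at 2.39 (SE 1.17). B cell genes (13 of 13, -3.67, 1.48e-11), plasma cell genes (9 of 10, -0.93, 0.00916) and MHC class II genes (10 of 10, -0.47, 0.00189) were lower, with BLK at -3.56 (SE 1.68) and MZB1 at -2.14 (SE 0.885). Ribosomal protein (73 of 76, -0.54, 3.28e-21), erythroid (16 of 17, -3.32, 4.97e-07) and immediate early genes, a list for sample handling (15 of 15, -0.50, 0.00124), were lower too. Non-classical monocyte (11 of 12, 1.0, 0.00206) and mature neutrophil genes (11 of 11, 0.97, 0.0318) were higher. As score changes per patient the exact permutation p was 0.257 for B cells, 0.286 for plasma cells, 0.0857 for MHC class II, 0.0857 for T cells and 0.0286 for NK cells (each 0.727 adjusted over 28 lists). The B cell difference came from no-TMA replicate 2 (5.12, others 0.185 and -0.0212) and TMA replicates 3 (-6.72) and 4 (-3.23), while the other TMA patients changed by 0.124 and 0.46. The lowest adjusted p with an estimated correlation was 0.574. The interferon gamma list was higher (30 of 32, 0.66, 8.78e-06) and the type I list lower (37 of 49, -0.43, 0.0374). The type I call ended without TMA replicate 1 (0.432) or 2 (0.0614), without no-TMA replicate 1 (0.173) and without the library no-TMA recovery replicate 1 (0.241), and its direction was up without no-TMA replicate 2 (0.273). The components (0.28, 0.093) passed without TMA replicate 2 (0.00365), and the receptors did not pass (0.42, 0.166). No gene passed with edgeR (616 had an unadjusted p under 0.05, lowest adjusted p 0.976) or limma-voom. DESeq2 called 2, which, chosen after their values were seen, were ANKRD33B (-2.05, SE 0.394, DESeq2 adjusted p 0.0017) and IL20RA (DESeq2 adjusted p 1.74e-05, edgeR unadjusted p 0.287).

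**Figure D4:**
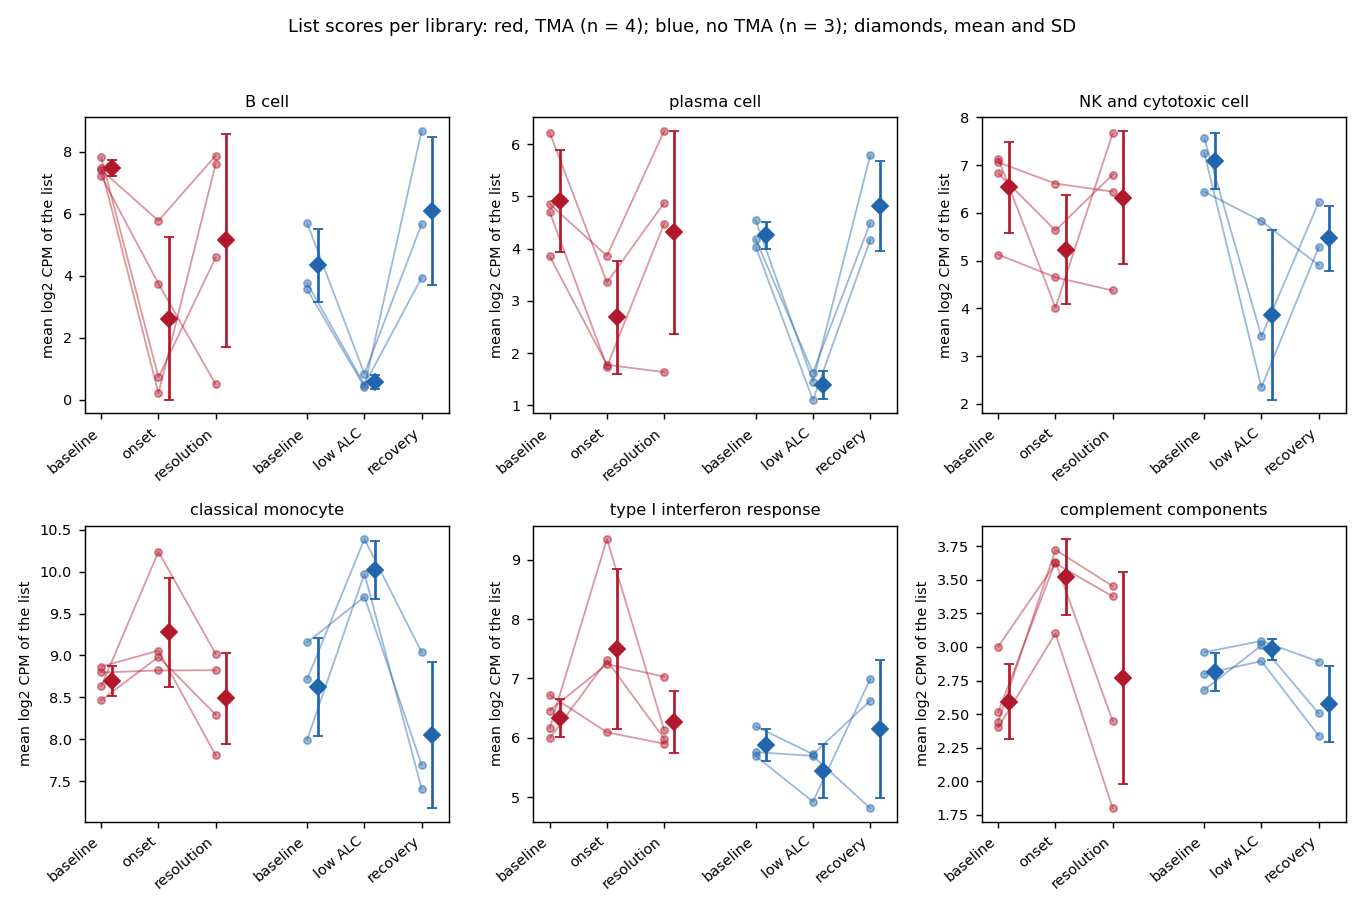
List scores (mean log2 CPM, y axis) of B cells, plasma cells, NK cells, classical monocytes, the type I interferon response and complement components at the 3 time points (x axis); thin lines join the libraries of a patient, and diamonds give the mean with the SD (n = 4 with TMA, n = 3 without). The mean B cell score was 7.48, 2.61 and 5.14 with TMA and 4.34, 0.576 and 6.09 without it.

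At baseline 332 genes passed between the arms with edgeR (179 higher and 153 lower with TMA), 1096 with DESeq2 and 428 with limma-voom. B cell genes were higher with TMA in 13 of 13 members (median 2.91, camera adjusted p 1.47e-33, estimated 0.312), of which 5 passed. CD24 (100133941) was higher by 3.39 (SE 0.3, adjusted p 0.000666), CD72 by 2.84 (SE 0.264, 0.000666) and CD79B by 2.57 (SE 0.334, 0.0064). CD24 stood at 104 ± 1.86 CPM (n = 4) with TMA and 9.96 ± 5 CPM (n = 3) without it. Other large differences were those of LCN10 (3.76, SE 0.437), NXPH4 (3.61, SE 0.662), DBNDD1 (3.32, SE 0.583) and FCRL2 (3.39, SE 0.603), and, lower, RNVU1-19 (-3.38, SE 0.341), FAM157C (-3.17, SE 0.385), GTF2IP20 (-2.94, SE 0.257), NR4A3 (-2.78, SE 0.519), PKD1P6 (-2.61, SE 0.243) and S100B (-2.44, SE 0.415). Ribosomal protein genes were higher in 74 of 76 (0.54, 3.05e-23, estimated 0.946), of which 6 passed with edgeR and 27 with DESeq2, and platelet genes lower in 15 of 15 (-0.57, 0.0262). The type I interferon list was higher in 47 of 49 (0.37, 6.1e-06, estimated 0.946), plasma cell genes in 8 of 10 (1.13, 0.0197) and MHC class II genes in 9 of 10 (0.45, 0.000785), while the complement components did not pass (-0.17, 0.639). These levels cannot be told apart from a difference between the tables, which coincide with the arms. The count was 70, 158, 168 and 215 without no-TMA replicate 2, TMA replicate 4, no-TMA replicate 1 and TMA replicate 1.

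At the second time point, TMA onset against low ALC, all 49 type I interferon members were higher with TMA (median 2.13, camera adjusted p 3.96e-32, estimated 0.566), of which 36 passed adjusted over the list alone and 0 over all genes, and 20 with DESeq2. SIGLEC1 was higher by 4.81 (SE 0.857, edgeR adjusted p 0.167), IFI27 by 4.83 (SE 0.712, 0.0909) and IFI44L by 4.97 (SE 1.27). The gamma list was higher in 31 of 32 (1.25, 7.42e-13) and the complement components in 10 of 14 (0.67, 0.00125, estimated 0.566), with C2 at 1.97 (SE 0.41). The regulators did not pass (0.14, 0.325), with SERPING1 at 4.09 (SE 1.18). T cell (18 of 18, 1.35, 4.06e-07), B cell (12 of 12, 3.87, 2.78e-05) and NK cell genes (15 of 16, 1.0, 0.000493) were higher, and immature neutrophil (14 of 17, -1.27, 1.15e-05) and classical monocyte genes (12 of 14, -0.51, 0.00121) lower. The B cell score overlapped between the arms: it was 5.77 and 3.74 in TMA replicates 2 and 3, and 0.211 and 0.722 in replicates 1 and 4, against 0.414 to 0.833 without TMA. With edgeR 11 genes passed, 1 higher (FRG1HP, 2.69, SE 0.337, adjusted p 0.0389) and 10 lower, against 283 with DESeq2 and 37 with limma-voom. None of the 11 is protein-coding, and 8 of them were near 0 CPM in every TMA library. The count was 6 without TMA replicate 2, 7 without TMA replicate 1 or 4 or no-TMA replicate 1 or 2, and 24 without TMA replicate 3. The tables coincide with the arms here too.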

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

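The tests of a single library, of classical and non-classical monocytes and of the tables were chosen after the results were seen. So were the score comparisons between the arms and all counts of splits. The tests of C1q and of members near the floor were set before their own values were seen, but after the score difference that they examine.

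Type I interferon genes were higher at TMA onset in all 49 members, but not evenly over the patients. One explanation is that 1 library carries the difference: the median fell from 1.16 to 0.406 without TMA onset replicate 3, so that library holds much of the size. The list still passed camera without it (adjusted p 0.00024). That call cannot show that a rise remains, because camera gave p values as small for this list in other splits of the libraries, counted below. Another is a larger share of monocytes: over the 7 patients the type I score change had r -0.528 with that of classical monocytes (exact permutation p 0.22; Spearman's rho -0.607, exact permutation p 0.167; r -0.218 without the 2 farthest patients) but r 0.87 with that of non-classical monocytes (exact permutation p 0.00159, 0.00556 adjusted over 7 relations; rho 0.893, exact permutation p 0.0123; r 0.597 without the 2 farthest patients). The permutation shuffled all 7 patients without regard to arm. Without TMA both scores fell in 3 of 3 patients (type I -0.768 to -0.0632, non-classical monocytes -1.49 to -0.298). The relation therefore also holds the difference between the arms. The interferon genes may come with more non-classical monocytes, or both may follow the same signal, which these libraries of mixed cells leave open. A biological difference between the patients at onset stays open and was not tested.

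The complement components score rose more from baseline to onset in patients with TMA than to low ALC in patients without it, by 0.759 log2 CPM (exact permutation p 0.0286, adjusted 0.622), which singled it out. Without C1QA, C1QB and C1QC the difference was 0.561 (exact permutation p 0.0286), made up of 0.314 ± 0.182 with TMA (higher in 4 of 4) and -0.247 ± 0.0927 without it (lower in 3 of 3), and the macrophage score differed by 0.0518 (exact permutation p 0.943), which argues against a larger share of C1q-carrying macrophages as the whole cause. Over the 12 members with a mean log2 CPM of at least 1 it was 1.01 (exact permutation p 0.0286), a size that argues against members near the detection floor. Both parts share members and patients with the score that was singled out by its p. Their p values are therefore no further evidence for the difference. A larger share of non-classical monocytes, whose score differed by 1.3 (exact permutation p 0.114), was not tested as a cause here and stays open. The value adjusted over the 28 lists of that change (0.622) cannot decide, because 35 splits cannot give a single list a p small enough to pass. The unadjusted p is reached by chance in 1 of 35 such tests, and 3 of the 84 score changes reached it. The time from transplant to the sample, which the labels do not give, stays open. A higher expression of complement genes with TMA is therefore a hypothesis, and a fall without TMA makes part of the difference (C3, chosen after its values were seen, changed by -0.808 with TMA and -2.5 without it).

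The tables differ in a way that follows the arms. There were 12 genes under 0.3 CPM in every library of one arm and over 2 CPM in every library of the other, against at most 1 in the other 34 splits of the patients. RCAN2-DT, for example, stood at a mean of 0 CPM with TMA and 50.6 without it, and NDUFV1-DT at 0 and 31.4, while BPIFB1 stood at 48 and 0.0103 (these genes were chosen after their values were seen). Of the 332 genes called at baseline 32.8% were not protein-coding, against 12.1% of the 15341 tested (Fisher's exact p 1.13e-23), with 62.1% among those lower and 7.82% among those higher with TMA. For these 12 genes the counts argue against a difference between the patients. The 11 present only without TMA, none protein-coding, had 0 to 10 counts in total over the 12 TMA libraries, against 515 to 13066 over the 9 others. BPIFB1 had 7768 counts with TMA and 2 without it. For the other genes called, processing with another annotation or library preparation and a difference between the patients cannot be told apart, since the tables coincide with the arms.

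The other values were singled out because 1 library lay far from the other 3 of its group, as 16 of 177 tested groups did, where chance flags about 1 in 20. At TMA baseline the mature neutrophil score of replicate 1 was 3.47 (the others 4.08 to 4.17). Its NK cell score was 5.13 (others 6.83 to 7.14). The inflammatory cytokine score of baseline replicate 2 was 4.76 (others 4.92 to 4.93). At TMA onset the complement components score of replicate 2 was 3.1 (others 3.62 to 3.72). The immature neutrophil score of onset replicate 4 was 4.04 (others -0.0893 to 0.603). Its classical monocyte score was 10.2 (others 8.82 to 9.06). The T cell score of onset replicate 3 was 3.24 (others 5.52 to 5.94). Its platelet score was 5.32 (others 2.67 to 3.05). The haemoglobin share of onset replicate 1 was 8.95% (others 0.0098% to 1.02%). The progenitor score of TMA resolution replicate 1 was 0.379 (others -0.0966 to -0.0352).

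Among changes per patient, the complement receptors score of TMA replicate 4 changed by 0.849 from baseline to onset (others 0.241 to 0.338). Its haem and oxidative stress score changed by 1.16 (others 0.363 to 0.421). From baseline to resolution its complement receptors score changed by 0.343 (others -0.271 to -0.184). The complement regulators score of TMA replicate 3 changed by -0.76 over the same interval (others 0.243 to 0.432). From onset to resolution the immature neutrophil score of replicate 4 changed by -4.12 (others -0.584 to -0.296), and its immediate early score by -1.69 (others 0.158 to 0.394). By chance, 1 in 35 score changes reaches the smallest exact permutation p, 0.0286. Between the arms, 3 of 84 did so before adjustment over the 28 lists of each change, which is near that share. Besides complement components these were the NK cell score from baseline to the last time point, with a difference of 1.41 (-0.216 ± 0.586 with TMA and -1.62 ± 0.327 without, adjusted 0.727), and the classical monocyte score from the second to the last, with a difference of 1.19 (-0.788 ± 0.587 and -1.98 ± 0.608, adjusted 0.8).

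Other splits of the libraries were counted for each test across genes. Within an arm the real split was compared with those that, like it, part every patient's pair; with TMA there are 8 and without it 4, too few for a share under 0.05. With edgeR, TMA onset against baseline had 0 genes in the real split and at most 0 in the others (8 of 8 as large), resolution against onset 0 and 0 (8 of 8), and resolution against baseline 0 and 0 (8 of 8). A real count of 0 makes every split as large, so these counts cannot tell. By genes with an unadjusted p under 0.05 the values were 2801 and 1083 (1 of 8), 1912 and 1798 (1 of 8), and 195 and 1266 (5 of 8). With DESeq2 the values were 1070 and 68 for onset against baseline (1 of 8) and 438 and 423 for resolution against onset (1 of 8). Without TMA, low ALC against baseline had 0 and 0 with edgeR (4 of 4) and 1138 and 2 with DESeq2 (1 of 4), recovery against low ALC 10 and 0 (1 of 4) and with DESeq2 1976 and 256 (1 of 4), and recovery against baseline 0 and 0 (4 of 4). By genes with an unadjusted edgeR p under 0.05 the values were 2562 and 301 (1 of 4), 3677 and 1352 (1 of 4), and 807 and 956 (2 of 4). Over all 35 edgeR splits with TMA, the rest of which leave both libraries of some patients on 1 side, the highest other counts were 0, 1 and 11 for the 3 comparisons in that order. Over all 10 without TMA they were 0, 0 and 1. For the lists at TMA onset the camera p of the real split and the lowest of the other splits were 6.22e-14 and 5.05e-46 for type I interferon (5 of 8), 1.5e-07 and 2.42e-17 for interferon gamma (4 of 8), 4.26e-05 and 0.00157 for components (1 of 8), 0.00073 and 0.00698 for receptors (1 of 8) and 0.0224 and 0.00391 for regulators (3 of 8).

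Between the arms the 7 patients have 35 splits. For the interaction at the second time point the real split had 0 genes and the highest other 31, and 35 of 35 were as large only because the real count is 0; by genes with an unadjusted p under 0.05, chance could not be excluded (739 and 1244, 8 of 35). A relabeling that calls 31 genes points to a structure among the patients, which was not tested further. Nor could chance be excluded for type I interferon (7.95e-25 and 3.61e-58, 9 of 35), interferon gamma (6.54e-15 and 2e-19, 5 of 35), receptors (0.72 and 0.000104, 30 of 35) or regulators (0.362 and 0.00268, 22 of 35). For the components, taken alone, the real split was the strongest by a small margin (0.00029 and 0.000324, 1 of 35), which excludes chance only without adjustment for the 5 lists counted, and their camera call ended without no-TMA replicate 3 (adjusted p 0.053) and with no filter (0.0713). Camera gave an unadjusted p under 0.05 for type I interferon in 31 of the 35 splits, for interferon gamma in 29 and for components in 11. For the interaction at the last time point the counts were 0 and 1, again with 35 of 35 as large because the real count is 0, and by unadjusted p chance could not be excluded (616 and 2315, 11 of 35). For the levels the real split called the most genes, at baseline (332 and 1, 1 of 35) and at the second time point (11 and 3, 1 of 35). This is the smallest share that 35 splits allow, and it was not adjusted for the number of comparisons. By genes with an unadjusted p under 0.05, 3 of 35 splits had as many at the second time point (1370 in the real split and 1569 in the highest other). Chance was therefore not excluded there. In both comparisons the tables coincide with the arms, and 8 of the 11 genes were near 0 CPM in every TMA library.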

How the results depend on the processing

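Limma-voom, bias-adjusted edgeR, removal of the haemoglobin genes and of single libraries were tests chosen after the data were seen, and the other alternatives were planned. RLE scaling gave 0, 0, 0, 0, 10, 0, 0, 0, 333 and 11 genes over the 10 comparisons in the order of the report, against 0, 0, 0, 0, 10, 0, 0, 0, 332 and 11 with TMM, and all 760 named gene values had the same direction and side of the threshold. Of named gene values, 567 of 760 were the same with DESeq2 and 192 newly passed, 3519 of 3731 were the same leaving out a patient (59 no longer passed) and 750 of 751 without the haemoglobin genes; none that had passed changed direction. The same held for 727 of 760 with limma-voom, 735 of 760 with bias-adjusted edgeR, 717 of 760 with no filter, 584 of 600 without the patient block, 429 of 447 in the joint fit and 1078 of 1126 without a single library. Of list results, 127 of 280 were the same with an estimated correlation and 153 no longer passed, with fry 119 were the same and 146 no longer passed, and leaving out a patient 205 of 245 were the same. In the changes below the cause was not tested, except that leaving out a patient also lowers the number of samples.

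DESeq2 called 1070 genes at TMA onset, 438 from onset to resolution, 1138 at low ALC, 1976 from low ALC to recovery, 57 at recovery against baseline, 3 and 2 in the interactions, 1096 at baseline between the arms and 283 at the second time point. Limma-voom called 6 at low ALC, 369 from low ALC to recovery and 37 at the second time point between the arms. Bias-adjusted edgeR called 14, 234 and 33 there, and 549 at baseline between the arms. Without a low-count filter the counts were 7 at TMA onset, 131 at low ALC, 492 from low ALC to recovery and 24 at the second time point between the arms. Without the patient block 1 gene passed at TMA onset, and 14 from low ALC to recovery, of which 5 were among the 10. The joint fit of all libraries called 179 at low ALC and 908 from low ALC to recovery.

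Leaving out a patient or a single library gave 0 to 365 genes at low ALC (365 without no-TMA replicate 3, 1 without replicate 2 and 3 without the library recovery replicate 1). From low ALC to recovery the range was 1 to 891 (1 without no-TMA replicate 1, 5 without replicate 2, 16 without replicate 3 and 891 without the library recovery replicate 1). Between the arms it was 70 to 404 at baseline (70 without no-TMA replicate 2, 158 without TMA replicate 4, 168 without no-TMA replicate 1, 215 without TMA replicate 1). At the second time point it was 6 to 24 (6 without TMA replicate 2, 7 without TMA replicate 1 or 4 or no-TMA replicate 1 or 2, 24 without TMA replicate 3).

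For the lists at TMA onset the adjusted p was, with an estimated correlation and with fry, 0.388 and 0.208 for type I interferon, 0.388 and 0.205 for interferon gamma, 0.174 and 0.0511 for components, 0.174 and 0.0511 for receptors and 0.351 and 0.158 for regulators. Leaving out a patient or library gave 9.5e-33 to 0.00024, 1.74e-12 to 0.0213, 1.83e-05 to 0.000481, 0.000456 to 0.00798 and 0.00105 to 0.179 (regulators: 0.057, 0.0683 and 0.0773 without TMA replicates 2, 3 and 4, and 0.179 without the library onset replicate 3). In the interaction the values were 0.504 and 0.572 for type I interferon (1.77e-47 to 5.29e-10), 0.504 and 0.572 for interferon gamma (2.79e-19 to 1.63e-06) and 0.454 and 0.572 for components (0.000212 to 0.053, the highest without no-TMA replicate 3; 0.0713 with no filter). Receptors there ranged over 0.292 to 0.845, with the direction down at 0.376 without no-TMA replicate 3 and 0.68 without TMA replicate 4, and regulators over 0.119 to 0.895.

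Patients and libraries were left out for the 5 interferon and complement lists. Where the list passed either as reported or in the alternative, the direction reversed for 4 results, all of interferon: type I at resolution against baseline without TMA replicate 1 (up, 0.0382; range over patients and libraries left out 0.00334 to 0.702), gamma from low ALC to recovery without no-TMA replicate 3 (up, 0.0491; range to 0.523), type I at recovery against baseline without no-TMA replicate 2 (down, 0.129; range from 5.29e-28) and type I in the last interaction without no-TMA replicate 2 (up, 0.273; range 1.49e-09 to 0.432). Directions of results that passed in neither also changed, in 12 values leaving out a patient, 1 leaving out a library, 1 with no filter and, over all 28 lists, 15 with fry. The effect of depth was not tested; genes near the floor at some time points, such as CD177, rest on few counts there.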

Other observations

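The tests of relations with the interferon and macrophage scores were set before their results were seen, and those with the non-classical monocyte score were chosen after.

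Platelet and red cell genes were examined because platelets and red cells are lost in TMA. The libraries are of blood mononuclear cells, so these genes do not show the number of platelets or red cells in blood. At the second time point neither list passed in the interaction (camera adjusted p 0.513 for each). Platelet genes were lower at TMA onset than at baseline in 15 of 15 members (median log2 fold change -1.34, camera adjusted p 0.00412, estimated 0.503) and at low ALC without TMA in 15 of 15 (-2.08, 1.44e-07, estimated 0.378), and higher again at resolution (1.19, 0.0075, estimated 0.547) and recovery (2.60, 4.87e-09, estimated 0.385). At TMA onset the platelet score was lower in 3 of 4 patients and 2.49 higher in replicate 3; PPBP stood at -1.40 (SE 1.87). Erythroid genes were higher at TMA onset in 16 of 16 (2.32, 0.00944, estimated 0.507) and at low ALC in 16 of 17 (2.36, 1.44e-07, estimated 0.423). Their score was higher in 3 of 4 patients with TMA, with a change of -3.38 in replicate 2, and in 3 of 3 without it. They were lower at resolution than at onset in 16 of 16 (-3.75, 3.23e-07, estimated 0.331), with SELENBP1 at -4.35 (SE 1.3), but the score was lower in 2 of 4 patients, with changes of -4.75 in replicate 1 and -5.38 in replicate 4, against 0.786 and 0.122 in the others. At recovery without TMA they stood above baseline (17 of 17, 2.03, 5.45e-07), with HBA2 at 2.67 (SE 0.803), a difference carried by the library recovery replicate 1 (score change 4.29, others 0.492 and -0.639). Genes of the endothelial list were lower at TMA onset in 6 of 6 members (-1.21, 0.00855, estimated 0.333), with MMRN1 at -2.06 (SE 0.42, DESeq2 adjusted p 0.000228) and TIE1 at -1.58 (SE 0.459) and the score lower in 3 of 4 patients, and at low ALC in 6 of 8 (-1.63, 0.0322). Like the platelet list, they were higher again at resolution (5 of 6, 1.0, camera adjusted p 0.0157) and at recovery (7 of 8, 0.93, 0.0473). The libraries are of blood mononuclear cells, and which cells carry these genes was not tested, so a change of endothelial cells is not shown. Coagulation genes did not pass at TMA onset (9 of 13 higher, 0.74, 0.0667, estimated 0.462), where PLAUR stood at 0.96 (SE 0.226, DESeq2 adjusted p 0.00592) and THBD at 1.10 (SE 0.46), and were lower at resolution than at onset (11 of 13, -0.87, 0.0103).

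Glucocorticoid response genes were higher at TMA onset in 12 of 12 members (median 1.34, camera adjusted p 0.00608, estimated 0.418), with FKBP5 at 1.86 (SE 0.806), mostly in 1 patient (score change 3.55 in replicate 1, others -0.338 to 0.645), and p53 targets in 16 of 16 (1.02, 0.000135, estimated 0.388), with TP53I3 at 0.86 (SE 0.256) and the score higher in 3 of 4 patients. Proliferation genes were higher at onset in 18 of 18 (1.5, 4.43e-07, estimated 0.388), with PCNA at 1.34 (SE 0.409), and were still higher at resolution than at baseline (1.60, 7.5e-24, estimated 0.642), with BUB1 at 2.15 (SE 0.698), the score in 3 of 4 patients both times. The haem and oxidative stress list was higher at onset in 13 of 13 (0.47, 8.19e-05, estimated 0.174). Ribosomal protein genes were lower at onset in 71 of 76 (-0.52, 9.15e-15, estimated 0.388). Inflammatory cytokines (0.71, 0.061), progenitor genes (-0.10, 0.296) and immediate early genes (-0.20, 0.253) did not pass at onset, where NLRP3 stood at 0.95 (SE 0.274) and IL6 at 2.55 (SE 1.08). Without TMA the low ALC values were 0.32 for the glucocorticoid list (0.0427), -0.01 for p53 targets (0.636, with the sign turning under RLE scaling), 1.03 for proliferation (6.29e-05), 0.67 for haem and oxidative stress (0.000323), 0.01 for ribosomal proteins (0.473), 0.22 for inflammatory cytokines (0.636), 0.07 for coagulation (0.323), 0.64 for progenitors (0.286) and -0.09 for immediate early genes (0.163). The 2 measured neuroblastoma genes had a median of 0.19 at TMA onset, without a test, and no mitochondrially encoded gene was in the tables.

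A hypothesis was that complement genes outside C1q move with interferon while C1q moves with macrophages. Of the genes used for the first part, SERPING1 also belongs to the interferon gamma list set beforehand, though not to the type I list. Over the 7 patients, the mean change of SERPING1, C2 and CFB from baseline to the second time point correlated with that of the type I interferon score (r 0.872, exact permutation p 0.0117, 0.0468 adjusted over 4 relations; Spearman's rho 0.75, exact permutation p 0.0663). The relation rests on the 2 patients farthest from the median, since r was 0.302 without them, and it was not tested within each arm. The mean change of the 3 genes was 0.524 to 2.72 with TMA and -0.676 to -0.202 without it. The highest value was that of TMA replicate 3, where SERPING1 went from 3.51 to 8.70 log2 CPM and C2 from 4.32 to 6.77. The relation is therefore in part that of an interferon gamma list member with the type I score. The interferon score also fell in all 3 patients without TMA, so r over the 7 patients also holds the difference between the arms. C1QA, C1QB and C1QC did not show a correlation with the interferon score that passed (r -0.0371, exact permutation p 0.94, adjusted 0.94; rho 0.214, exact permutation p 0.662; 0.359 without the farthest). Their relation with the macrophage score did not pass either (r 0.625, exact permutation p 0.16, adjusted 0.319; rho 0.357, exact permutation p 0.444; 0.665 without the farthest), nor did that of SERPING1, C2 and CFB (r -0.445, exact permutation p 0.316, adjusted 0.421; rho -0.429, exact permutation p 0.354; 0.533 without the farthest). The change of SERPING1, C2 and CFB followed that of the non-classical monocyte score at least as closely (r 0.928, exact permutation p 0.000992, 0.00556 adjusted over 7 relations; rho 0.929, exact permutation p 0.00675; 0.747 without the farthest). All 3 patients without TMA were also lower in the non-classical monocyte score, so this r holds the difference between the arms as well. These genes may follow interferon (r 0.872) or the share of non-classical monocytes (r 0.928), or differ only with the arm, which these data do not separate.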
